A study of Rattus norvegicus with 8 samples.

How the data were processed

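RNA was extracted with TRIzol from the cervix of pregnant Sprague-Dawley rats and sequenced as 8 libraries, 4 from animals injected with phosphate-buffered saline (PBS) and 4 from animals injected with lipopolysaccharide (LPS). The series' design text calls the 4 libraries of a group biological replicates. The libraries were made with the VAHTS Universal V6 kit from total RNA, per the labels' protocols. The authors deposited raw counts, 1 whole number per gene symbol and library. The submitters' processing notes name fastp, HISAT2, HTSeq, R 3.2.0 and the build mRatBN7.2 without saying what each step did. The strand setting and the annotation are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies such as the globin, Serpinb3 and Saa genes, could not be told apart. Genes are given by symbol, as deposited, and no coordinates are printed. Columns were matched to samples through the library names in the labels, in which LPS replicate 4 carries the number 5.

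The table held 29884 gene symbols, of which 22854 had at least 1 count. Totals ranged from 33191039 to 40634384 counts per library, and 3 counts corresponded to between 0.0734 and 0.0899 CPM (counts scaled to a library of 1e6). Intervals and floors cover counting error only.

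Genes were kept by edgeR's filterByExpr by group, which left 16117 genes. Library sizes were scaled by the trimmed mean of M values (TMM), and levels are given as TMM-scaled CPM, mean ± SD over 4 libraries. LPS and PBS were compared with edgeR 4.0.16 in R 4.3.3, with robust quasi-likelihood fits and F tests, no covariate, and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of F. All fold changes are LPS minus PBS on the log2 scale, and adjusted p-values of single genes in the text come from this test unless another is named.

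A set of 27 gene lists, including markers of other cell types that a piece of cervix can hold, was fixed before the data were examined, as were the tests, the alternatives and the rule for the genes named. Of the 503 list entries, 4 had no row in the table and 49 fell below the filter. Lists were tested with edgeR's camera at a preset correlation between genes of 0.01, adjusted over the 27 lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. The number of called members is given over all genes tested and adjusted over the list alone.

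The named genes were, first, the 5 largest rises and the 5 largest falls among called genes with a mean of at least 1 CPM, no overlap between groups and a symbol that is no placeholder, second, the 2 members with the lowest adjusted p among the called members of each list, and last, a fixed set of 17 genes of inflammation, contraction, steroid signalling and matrix turnover, whatever their result. The rule took 73 genes. 1 of them is not reported here. Genes named outside it are said to have been chosen after their values were seen.

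Principal components were computed from the 500 most variable genes on log2 CPM with a prior count of 2. The share of a component's variance between groups, and differences in library measures, were tested with exact two-sided permutation tests. With 4 libraries against 4 these cannot give a p below 0.0286.

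The gene and list tests were tested on simulated data drawn from the means and library sizes of these libraries. Of 100 genes changed 2-fold, 58% were called with the right sign, and of 100 genes changed 4-fold, 84%. In that step 200 of the simulated genes were changed, 15927 were tested, and 13 unchanged ones were called. The 13 are to be set against the changed genes called, not against all genes tested. In the data 16.9% of the genes tested were called, a far larger share than was changed here. The rates of this simulation thus need not hold for the data. Camera called a list shifted 1.5-fold and 0 of 26 unshifted lists, in data simulated without correlation between genes.

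The alternatives were RLE and upper-quartile scaling, no filter on low counts, a filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom 3.58.1 with and without library quality weights, each library left out in turn, and the replicate number as a block. For principal component 1 they were all tested genes, RLE scaling and a prior count of 0.5. An alternative without PBS replicate 1 and LPS replicate 2, in which most neuron genes were lowest, was added after seeing the data. A further 10 lists were chosen with the data in hand and are used in the closing section only.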

Results

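The cervix of pregnant rats was profiled by RNA sequencing 12 hours after an intraperitoneal injection given on gestational day 17. The comparison asks which transcripts of the cervix change when a bacterial stimulus that is used to bring on preterm birth is given. LPS, a glycolipid of the outer membrane of Gram-negative bacteria, was given at 100 µg/kg to the animals of the LPS group, and the controls received the same volume of PBS. Each group held 4 libraries. Total counts lay between 39580706 and 40408153 in LPS and between 33191039 and 40634384 in PBS, where replicate 4 was the shallowest. Of the 22854 genes with any count, 16117 were tested.

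12 hours after LPS, 28 of 29 tested interferon response genes, 11 of 19 complement genes and 8 of 15 acute phase genes were higher, and 1 of the acute phase genes was lower. Lower were 8 of 15 smooth muscle markers, 6 of 11 red cell markers and 4 of 16 squamous epithelium markers, and 0 of these were higher. With 1 library left out, the smooth muscle count ran from 1 (without LPS replicate 1) to 15 (without PBS replicate 4) and the red cell count from 0 (without PBS replicate 2) to 6. As lists, these 6 were not called by camera with an estimated correlation (adjusted p of 0.0732 to 0.338), which called 0 of 27 lists. Lcn2, which binds the iron carriers of bacteria, rose from 188 ± 86.3 to 3089 ± 820 CPM (mean ± SD, n = 4 per group), and Krt13, a keratin of stratified squamous epithelium, fell from 2197 ± 935 to 94.9 ± 48.5 CPM. In all, 1529 genes were higher and 1200 lower, which is 16.9% of those tested, and 764 and 506 of them changed at least 2-fold. The count of higher genes was 904 without PBS replicate 2. That of lower genes was 563 without PBS replicate 2, 752 without PBS replicate 3, 750 without LPS replicate 3 and 2089 with DESeq2, and that of genes at least 2-fold lower was 295 without PBS replicate 2. Without both PBS replicate 1 and LPS replicate 2, an alternative chosen after seeing the data, 1137 genes were higher and 873 lower.

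Principal component 1 held 58.5% of the variance of the 500 most variable genes, and 0.98 of its variance lay between the groups (exact permutation p = 0.0286 over 70 permutations, the smallest they can give). Component 2, with 16.3%, set PBS replicate 1 and LPS replicate 2 apart from the other libraries. Correlations of log2 CPM ran from 0.963 to 0.979 within PBS, from 0.961 to 0.972 within LPS and from 0.921 to 0.951 between the groups. Every pair of libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 57.3. Transcripts of the mitochondrial genome made up 6.62 ± 0.990% of counts in PBS and 4.71 ± 0.401% in LPS (exact permutation p = 0.0286, n = 4 per group).

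**Figure D1:**
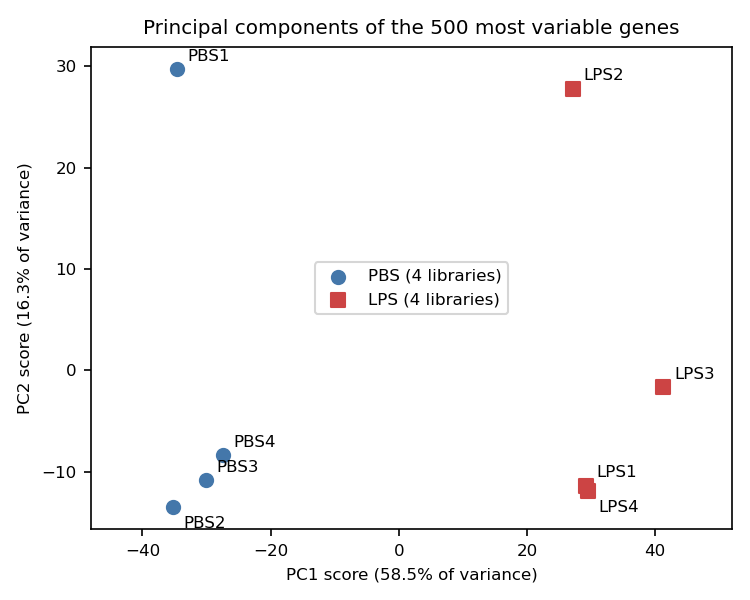
Scores of the 8 libraries on principal components 1 and 2 of the 500 most variable genes (log2 CPM, centred), circles for PBS and squares for LPS. Component 1, with 58.5% of the variance, separates the groups, and PBS1 and LPS2 lie apart from the other libraries on component 2, with 16.3%.

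Among genes that met the rule for the largest changes, Saa3, an acute phase protein, rose most, from 0.771 ± 0.452 to 333 ± 104 CPM (n = 4 per group), a log2 fold change of 8.76 (SE 0.52, adjusted p = 0.000252). Mmp9, gelatinase B of neutrophils and macrophages, rose from 0.314 ± 0.256 to 40.9 ± 16.3 CPM, or by 7.06 (SE 0.57, adjusted p = 0.0004). The long pentraxin Ptx3 rose by 7.06 (SE 1.29, adjusted p = 0.0087), with 670 CPM in LPS replicate 3 and at most 56.7 CPM in the other LPS libraries, and by 4.86 without that library. Serpinb3a, a protease inhibitor with close copies, rose by 7.19 (adjusted p = 0.00226), or by 6.46 without LPS replicate 3. It had 1591 counts in LPS against 10 in PBS, a ratio of 153 (95% counting interval 82.8 to 319). Pglyrp3, which binds bacterial peptidoglycan, also rose (adjusted p = 0.00267), and its 368 counts in LPS against 2 in PBS give a ratio of 177 (95% counting interval 48.5 to 1464). The largest falls were those of Spink7, an epithelial protease inhibitor, from 6.78 ± 8.26 to 0.0811 ± 0.071 CPM (log2 fold change -6.33, adjusted p = 0.00762), and of Cyp26a1, which breaks down retinoic acid, from 16.4 ± 17.2 to 0.252 ± 0.152 CPM (-6.02, adjusted p = 0.004). Ltc4s, leukotriene C4 synthase, fell by 5.77 (adjusted p = 0.00286). Its 346 counts in PBS against 6 in LPS give a ratio of 60.1 (95% counting interval 27.3 to 165). Abcb1b, a drug efflux pump, fell from 588 ± 599 to 13.2 ± 6.2 CPM (-5.48, adjusted p = 0.00605), and Adprhl1 fell by 5.42 (adjusted p = 0.00641). PBS replicate 1 held the most Cyp26a1, Abcb1b and Adprhl1, and without it their log2 fold changes were -4.98, -4.52 and -4.23. That of Spink7 was -5.02 without PBS replicate 2 and -6.99 without LPS replicate 1. Limma-voom did not call Serpinb3a, Ptx3, Spink7 or Cyp26a1.

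Of the 27 lists, 12 were higher and 6 lower under camera's preset correlation. With an estimated correlation camera called 0 lists, with 6 higher and 0 lower at an unadjusted p under 0.05, while fry called 10 higher and 3 lower. Other splits of the same 8 libraries into 4 and 4 reached up to 20 called lists under the preset correlation, so the counts of single genes are given for each list.

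Of 20 tested cytokines and chemokines, 12 rose and 0 fell (15 and 0 adjusted over the list alone), with a median log2 fold change of 2.94 (camera adjusted p = 1.26e-08, adjusted p = 0.258 with an estimated correlation) and of 2.25 without LPS replicate 3. Il1b, a central inflammatory cytokine, rose from 13.9 ± 6.8 to 64.3 ± 17.7 CPM (n = 4 per group; log2 fold change 2.21, SE 0.34, adjusted p = 0.00435). Tnf rose by 1.999 (adjusted p = 0.0189), or by 2.61 without PBS replicate 4, and was not called without both PBS replicate 1 and LPS replicate 2. The monocyte attractant Ccl2 rose from 2.88 ± 0.702 to 95.8 ± 131 CPM (adjusted p = 0.00929), and Ccl4 rose by 4.59 (adjusted p = 0.00279). LPS replicate 3 held 291 CPM of Ccl2, and without it the log2 fold changes were 3.41 for Ccl2 and 3.83 for Ccl4. The value of Il6 was 3.77 (adjusted p = 0.0961), with 18.7 CPM in LPS replicate 3 and 0.384 to 1.98 CPM in the other LPS libraries, and 1.37 without LPS replicate 3. That of the neutrophil attractant Cxcl1 was 3.23 (adjusted p = 0.0523). It passed the threshold without PBS replicate 4 (4.35, adjusted p = 0.0253) or without LPS replicate 2 (3.54, adjusted p = 0.0472). DESeq2 called both Il6 and Cxcl1, the weighted limma-voom fit called Cxcl1, and limma-voom did not call Ccl2.

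Of the 23 genes of the TLR4 and NF-kB pathway, 15 rose and 1 fell (19 and 1 adjusted over the list alone), with a median of 1.10 (camera adjusted p = 1.03e-12, adjusted p = 0.0949 with an estimated correlation). The NF-kB subunits Relb and Nfkb2 rose by 2.12 (SE 0.17, adjusted p = 0.0004) and 1.10 (SE 0.11, adjusted p = 0.000864). Nos2, the inducible nitric oxide synthase, rose from 3.12 ± 1.25 to 49.9 ± 47.3 CPM (adjusted p = 0.0103). Its log2 fold change was 3.9985, or 3.16 without LPS replicate 4, and neither limma-voom fit called it. The gene that fell was Tlr4, the receptor for LPS, by 0.35 (adjusted p = 0.0446). It was named after its value was seen, and its call was lost without any one of PBS replicates 2, 3 and 4 and LPS replicates 1, 2 and 3. Of the 15 genes of pyroptosis and the inflammasome, 11 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 1.10 (camera adjusted p = 7.4e-12, adjusted p = 0.0677 with an estimated correlation). Among them were Casp1, which cleaves pro-interleukin-1 beta (1.22, adjusted p = 0.0004), and Casp4, which senses LPS in the cytosol (2.13, adjusted p = 0.0014).

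The interferon response rose almost throughout: 28 of 29 tested genes rose and 0 fell, and so they did adjusted over the list alone. The median was 1.71 (camera adjusted p = 6.8e-45, adjusted p = 0.0732 with an estimated correlation). The antiviral GTPase Mx1 rose from 49.8 ± 8.45 to 359 ± 112 CPM (n = 4 per group; log2 fold change 2.85, SE 0.23, adjusted p = 0.0004) and Oasl by 2.52 (adjusted p = 0.0004). The gene that did not pass was Ifit1, named after its values were seen (3.13, adjusted p = 0.224). LPS replicate 3 held 0.532 CPM of it against 68.6 to 97.0 CPM in the other LPS libraries, and PBS replicate 1 held 26.7 CPM against at most 0.468 CPM in the other PBS libraries. Without PBS replicate 1 its log2 fold change was 7.46 (adjusted p = 0.0216).

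Of 15 acute phase genes, 8 rose and 1 fell (9 and 2 adjusted over the list alone), with a median of 1.84 (camera adjusted p = 1.26e-08, adjusted p = 0.0888 with an estimated correlation) and of 0.90 without LPS replicate 3. Besides Lcn2 (4.04, SE 0.42, adjusted p = 0.000946), Steap4, a metalloreductase, rose from 139 ± 3.89 to 589 ± 66.5 CPM (2.09, SE 0.10, adjusted p = 0.000133). The gene that fell was Fga, a fibrinogen chain, by 3.54 (adjusted p = 0.029). It was named after its value was seen. Its call was lost without PBS replicate 1 or 2 or LPS replicate 2 or 3, and leaving out PBS replicate 1 or LPS replicate 1 moved its value over 1.5 times, within -4.14 to -2.68. Of 19 complement genes, 11 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.72 (camera adjusted p = 3.96e-16, adjusted p = 0.0732 with an estimated correlation). The proteases of the C1 complex C1s and C1r rose from 259 ± 22.1 to 1375 ± 178 CPM and from 365 ± 33 to 1724 ± 284 CPM. C3, the component on which the pathways meet, rose by 1.97 (SE 0.20, adjusted p = 0.000838).

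Of 11 tested neutrophil markers, 8 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 2.24 (camera adjusted p = 1.8e-08, adjusted p = 0.215 with an estimated correlation). Without PBS replicate 2 the count was 4, and without PBS replicate 1 or 4 it was 5. The list held 20 markers, and the rest, among them Elane, Ltf, Camp and Cxcr1, fell below the filter on low counts. S100a9, a subunit of calprotectin, rose from 15.3 ± 3.8 to 489 ± 248 CPM (n = 4 per group; 5.0043, SE 0.44, adjusted p = 0.000568), and Cd177 rose by 4.80 (adjusted p = 0.000977). S100a8, the partner of S100a9, rose by 5.20 (adjusted p = 0.00164), or by 4.57 without LPS replicate 4, and the neutrophil collagenase Mmp8 by 5.94 (adjusted p = 0.00644), or by 4.42 without LPS replicate 4, which held 115 CPM of it. Neither limma-voom fit called Mmp8. Of 16 macrophage and monocyte markers, 10 rose and 2 fell (12 and 2 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 8.5e-10, adjusted p = 0.0949 with an estimated correlation). Adgre1, which encodes F4/80, rose from 22.8 ± 1.96 to 322 ± 184 CPM (3.82, adjusted p = 0.000761), and the Fc receptor Fcgr1a rose by 1.43 (adjusted p = 0.000858). Those that fell, named after their values were seen, were Ccr2, a receptor for Ccl2 (-1.38, adjusted p = 0.0292), and the hyaluronan receptor Lyve1 (-1.01, adjusted p = 0.0166). The call of Lyve1 was lost without PBS replicate 2 and that of Ccr2 without PBS replicate 1, 2 or 3 or LPS replicate 1. Of 19 T, NK and B cell markers, 4 rose and 0 fell, and so they did adjusted over the list alone (median 0.36, camera adjusted p = 0.0701). Gzmb alone rose without PBS replicate 2, and 2 rose without PBS replicate 1, LPS replicate 1 or LPS replicate 4. The list passed without PBS replicate 3 (median 0.61, adjusted p = 0.00389), with no filter on low counts and with the stricter filter. The cytotoxic granule genes Gzmb and Prf1 rose by 3.21 (adjusted p = 0.0107) and 1.72 (adjusted p = 0.0177), and the call of Prf1 was lost without PBS replicate 2 (1.54, adjusted p = 0.0523).

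**Figure D2:**
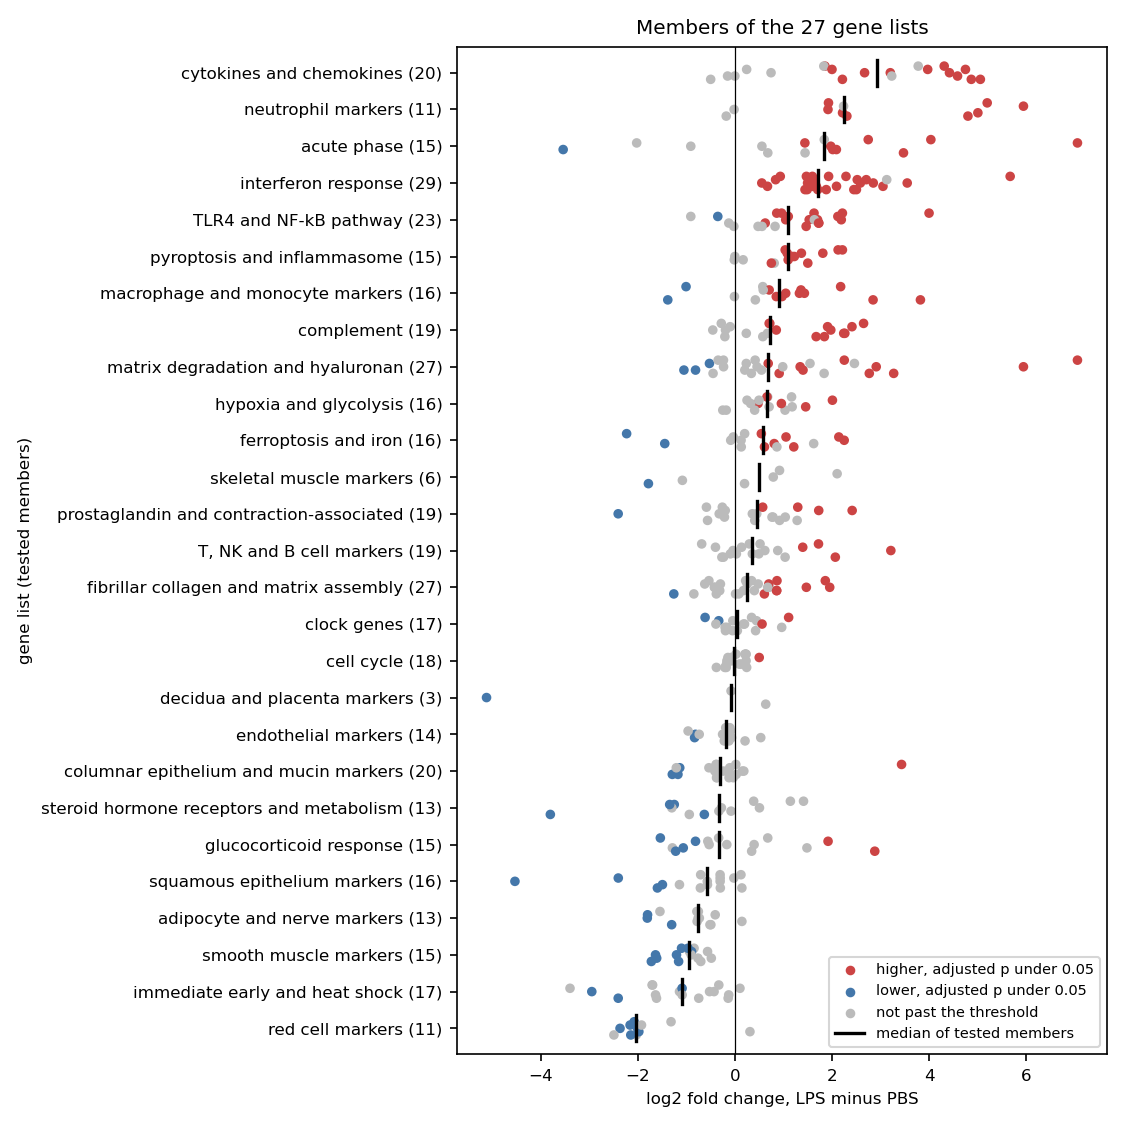
Log2 fold changes (LPS minus PBS) of the tested members of the 27 gene lists, with the number of tested members in parentheses and a black line at each list's median. Red points were higher and blue points lower at an adjusted p under 0.05, and grey points did not pass. The medians run from -2.03 for red cell markers to 2.94 for cytokines and chemokines.

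Of 16 genes of ferroptosis and iron, 7 rose and 2 fell (9 and 2 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 0.00116, adjusted p = 0.325 with an estimated correlation). Fth1, the ferritin heavy chain, rose from 1715 ± 109 to 3556 ± 497 CPM (n = 4 per group; 1.05, adjusted p = 0.00148), and Lpcat3 rose by 0.81 (adjusted p = 0.00154). Those that fell, named after their values were seen, were Slc40a1, the iron exporter ferroportin (-1.45, adjusted p = 0.00381), and the lipoxygenase Alox15 (-2.23, adjusted p = 0.0375). The call of Alox15 was lost without any one of 6 libraries, PBS replicates 1 and 2 and the 4 of LPS, and its value was -1.48 without PBS replicate 1. Of 16 genes of hypoxia and glycolysis, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 0.00074, adjusted p = 0.426 with an estimated correlation, fry adjusted p = 0.0658). The count was 2 without PBS replicate 2 or LPS replicate 1, and 3 without PBS replicate 1 or 4 or LPS replicate 3 or 4. Pgk1, a glycolytic kinase, rose by 1.46 (adjusted p = 0.00184) and the carbonic anhydrase Car9 by 2.01 (adjusted p = 0.0134).

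Matrix genes moved both ways. Of 27 genes of matrix degradation and hyaluronan, 10 rose and 3 fell (13 and 3 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 0.000136, adjusted p = 0.212 with an estimated correlation). Besides Mmp9, the metalloproteinase inhibitor Timp1 rose from 99.4 ± 11.6 to 747 ± 317 CPM (n = 4 per group; 2.91, adjusted p = 0.000885). Those that fell, named after their values were seen, were the hyaluronidases Hyal1 (-1.05, adjusted p = 0.00752) and Hyal2 (-0.53, adjusted p = 0.0121) and the inhibitor Timp3 (-0.81, adjusted p = 0.00553). Without LPS replicate 2, 5 fell. The hyaluronan synthase Has2 had a value of 0.98 (adjusted p = 0.126), or 0.37 without LPS replicate 3, which held 20.3 CPM. Of 27 genes of fibrillar collagen and matrix assembly, 8 rose and 1 fell (8 and 4 adjusted over the list alone). The count of those that rose was 4 without PBS replicate 3 or 4 and 5 without PBS replicate 2 or LPS replicate 2, and 2 fell without PBS replicate 3. The small proteoglycans decorin (Dcn) and lumican (Lum) rose from 1245 ± 34.2 to 3449 ± 787 CPM and from 167 ± 36.2 to 646 ± 220 CPM. Loxl4, a lysyl oxidase named after its value was seen, fell by 1.26 (adjusted p = 0.0338), a call lost without PBS replicate 2 or 3 or any one of the 4 LPS libraries. The list's median was 0.25 (camera adjusted p = 0.0399, adjusted p = 0.52 with an estimated correlation, fry adjusted p = 0.107). Its call was lost without PBS replicate 3 (median 0.20, adjusted p = 0.18), PBS replicate 4 (0.27, adjusted p = 0.0881) or LPS replicate 2 (0.08, adjusted p = 0.149), and without both PBS replicate 1 and LPS replicate 2.

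Of 19 genes of prostaglandins and contraction, 4 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.45, camera adjusted p = 0.128), and 2 fell without PBS replicate 4. The oxytocin receptor Oxtr fell from 17.5 ± 6.74 to 3.29 ± 1.56 CPM (n = 4 per group; -2.41, SE 0.40, adjusted p = 0.00563). Gja1, the gap junction protein connexin 43, rose from 56.1 ± 13.2 to 185 ± 103 CPM (1.73, SE 0.35, adjusted p = 0.013), and the endothelin receptor Ednra rose by 1.29 (adjusted p = 0.00553). Ptgs2, the inducible cyclooxygenase, had a value of 1.04 (adjusted p = 0.0925). It passed without PBS replicate 4, which held 37.3 CPM (1.43, adjusted p = 0.0269), with DESeq2 and with the weighted limma-voom fit. Of 13 genes of steroid receptors and metabolism, 0 rose and 4 fell, also adjusted over the list alone (median -0.33, camera adjusted p = 0.0651). Without PBS replicate 1 or 2 or LPS replicate 1 or 4, 2 fell, and 1 rose without LPS replicate 4. The list passed without LPS replicate 2 (median -0.48, adjusted p = 0.00918) and without both PBS replicate 1 and LPS replicate 2. Greb1, a target of the estrogen receptor, fell by 1.25 (adjusted p = 0.011) and the mineralocorticoid receptor Nr3c2 by 1.34 (adjusted p = 0.0114). The progesterone receptor Pgr fell by 0.63 (SE 0.17, adjusted p = 0.037), from 112 ± 5.2 to 72.2 ± 19.9 CPM. That call was lost when any one library other than LPS replicate 2 was left out, with values of -0.66 to -0.53. The estrogen receptor Esr1 had a value of 0.39 (adjusted p = 0.142). Of 15 glucocorticoid response genes, 2 rose and 4 fell (2 and 5 adjusted over the list alone), with a median of -0.34, a mean of 0.01 and a camera adjusted p of 0.291. Of them 1 rose without PBS replicate 2 or 3, and 2 fell without PBS replicate 2 or LPS replicate 1 or 2. The lipase inhibitor Angptl4 rose by 2.88 (adjusted p = 0.0026) and the co-chaperone Fkbp5 fell by 1.22 (adjusted p = 0.00436). Of 17 clock genes, 2 rose and 2 fell (3 and 3 adjusted over the list alone; median 0.05, camera adjusted p = 0.80), among them Nr1d1 (0.56, adjusted p = 0.00875) and Clock (-0.33, adjusted p = 0.0123). 1 clock gene rose without PBS replicate 2 or 4 or any one LPS library, and 1 fell without PBS replicate 1 or 2 or LPS replicate 1, 2 or 3.

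**Figure D3:**
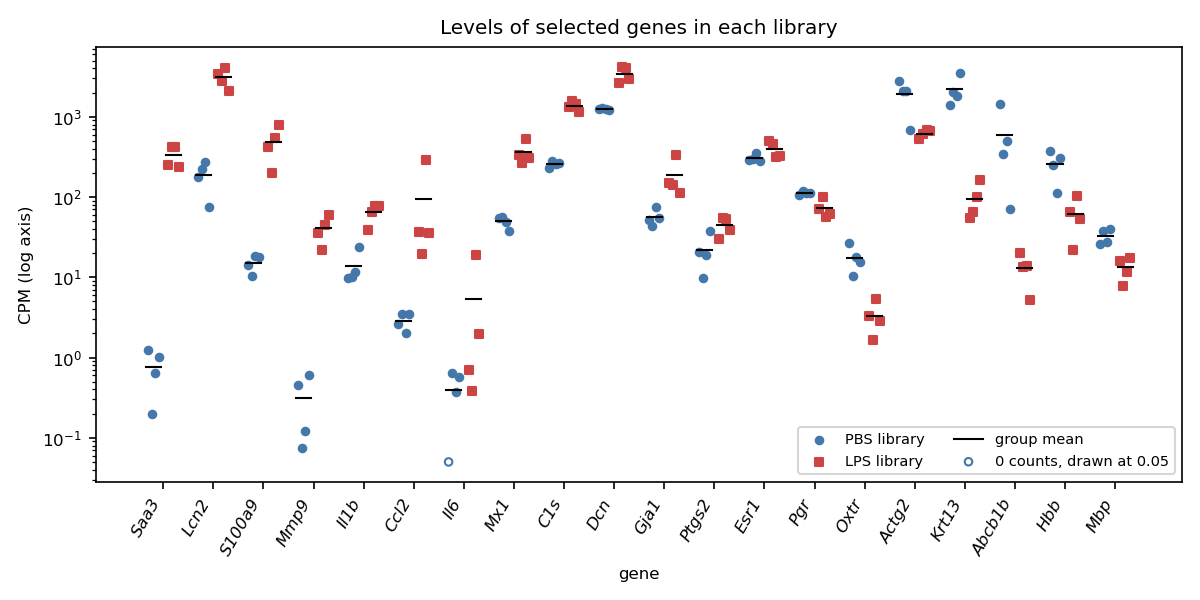
CPM (log axis) of 20 genes in each library, circles for the 4 PBS and squares for the 4 LPS libraries, with a line at each group mean. Saa3 lies at 0.771 CPM on average in PBS and at 333 CPM in LPS, Krt13 at 2197 and 94.9 CPM, and single libraries such as LPS replicate 3 for Ccl2, at 291 CPM, stand apart.

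Smooth muscle markers were lower: 8 of 15 fell and 0 rose over all genes tested, and 14 fell adjusted over the list alone, with a median of -0.94 (camera adjusted p = 6.1e-07, adjusted p = 0.338 with an estimated correlation, fry adjusted p = 0.0562). The count was 15 without PBS replicate 4, whose mean log2 CPM of these markers (7.69) lay within that of the LPS libraries. It was 1 without LPS replicate 1, 2 without PBS replicate 2 or LPS replicate 3, 3 without PBS replicate 3, and 4 without PBS replicate 1 or LPS replicate 2. Actg2, the actin of visceral smooth muscle, fell from 1920 ± 885 to 617 ± 71.7 CPM (n = 4 per group; -1.64, adjusted p = 0.0181), with 686 CPM in PBS replicate 4. Its call was lost without PBS replicate 2 (-1.60, adjusted p = 0.0522) or LPS replicate 1 (-1.56, adjusted p = 0.0501). Synm, an intermediate filament protein, fell by 1.72 (adjusted p = 0.0133), and neither gene was called without both PBS replicate 1 and LPS replicate 2. Of 16 squamous epithelium markers, 4 fell and 0 rose (6 and 0 adjusted over the list alone), with a median of -0.57 (camera adjusted p = 0.000183, adjusted p = 0.325 with an estimated correlation). Besides Krt13 (-4.53, SE 0.45, adjusted p = 0.000846), Krt1, a keratin of cornifying layers, fell by 2.40 (adjusted p = 0.00607). Of 20 markers of columnar epithelium and mucins, 3 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 0.0166, adjusted p = 0.426 with an estimated correlation, fry adjusted p = 0.0658). The list's call was lost without PBS replicate 4 (median -0.12, adjusted p = 0.0786). Krt7 fell by 1.17 (adjusted p = 0.0018), and the gel-forming mucin Muc5ac rose from 8.1 ± 6.04 to 87.0 ± 56.5 CPM (3.43, adjusted p = 0.00872), or by 4.04 without PBS replicate 4. The far more abundant gel-forming mucin Muc5b, named after its value was seen, was not called (0.03, adjusted p = 0.934). It lay at 18412 CPM in PBS and 18762 CPM in LPS.

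Of 11 red cell markers, 6 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of -2.03 (camera adjusted p = 4.06e-05, adjusted p = 0.325 with an estimated correlation). The count was 0 without PBS replicate 2 and 1 without LPS replicate 1 or 4. The globin genes Hbb and Hba-a3 fell from 259 ± 109 to 61.3 ± 33.8 CPM and from 23.3 ± 9.08 to 5.79 ± 3.35 CPM (n = 4 per group; adjusted p = 0.0228 and 0.0229). Reads of globin copies could be shared. The call of Hbb was lost without PBS replicate 2 (-2.09, adjusted p = 0.0558), LPS replicate 1 (-2.11, adjusted p = 0.0538) or LPS replicate 4 (-2.02, adjusted p = 0.0546), and that of Hba-a3 without PBS replicate 2 (-2.04, adjusted p = 0.0555) or LPS replicate 2 (-1.86, adjusted p = 0.0546). Hba-a3 was also not called without both PBS replicate 1 and LPS replicate 2 (-1.595, adjusted p = 0.0911). Of 13 adipocyte and nerve markers, 3 fell and 0 rose (4 and 0 adjusted over the list alone), with a median of -0.76 (camera adjusted p = 0.00116, adjusted p = 0.325 with an estimated correlation). The myelin gene Mbp fell by 1.30 (adjusted p = 0.0115). Of 17 immediate early and heat shock genes, 3 fell and 0 rose, also adjusted over the list alone, with a median of -1.09 (camera adjusted p = 0.00622, adjusted p = 0.52 with an estimated correlation, fry adjusted p = 0.222) and of -0.06 without PBS replicate 4 (adjusted p = 0.244). In this list 1 gene fell without PBS replicate 2 or 4 or LPS replicate 1, 2 or 3, and 1 rose without PBS replicate 4. The small heat shock gene Hspb1 fell by 1.09 (adjusted p = 0.00726). Fosb fell by 2.95 (adjusted p = 0.0301), with 29.8 CPM in PBS replicate 4. Its call was lost without PBS replicate 2 or 4 or LPS replicate 1, 2 or 3, and its value was -2.18 without PBS replicate 4 and -3.56 without LPS replicate 4. Neither limma-voom fit called Fosb.

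The remaining lists did not pass. Of 14 endothelial markers, 2 fell and 0 rose (4 and 0 adjusted over the list alone; median -0.18, camera adjusted p = 0.124), and the list passed without PBS replicate 3 (-0.29, adjusted p = 0.0321) or PBS replicate 4 (-0.34, adjusted p = 0.00542). Of these markers 4 fell without PBS replicate 4, and 1 rose without PBS replicate 2. Cldn5 and Emcn fell by 0.81 (adjusted p = 0.0242) and 0.83 (adjusted p = 0.0375). Without PBS replicate 2 the adjusted p was 0.0719 for Cldn5 and 0.0983 for Emcn, and their calls were also lost without LPS replicate 3 (0.062 and 0.0931) or LPS replicate 4 (0.0516 and 0.0546), that of Emcn also without LPS replicate 1 or 2. Of 18 cell cycle genes, 1 rose and 0 fell, also adjusted over the list alone, and it was Mcm2 (0.50, adjusted p = 0.0172). Their median was -0.02, their mean 0.02 and the direction of the test up (camera adjusted p = 0.89). Of 6 skeletal muscle markers, 1 fell and 0 rose (2 and 1 adjusted over the list alone), with a median of 0.49, a mean of 0.19 and a test that pointed down (camera adjusted p = 0.955). Acta1 fell by 1.78 (adjusted p = 0.0247), a call lost without PBS replicate 2 (-1.59), LPS replicate 1 (-1.61), LPS replicate 2 (-1.77) or LPS replicate 4 (-1.75). Without both PBS replicate 1 and LPS replicate 2 it was not called either (-1.58, adjusted p = 0.0931). In that list 1 gene rose without PBS replicate 1. Of 3 tested decidua and placenta markers, 1 fell and 0 rose, also adjusted over the list alone (median -0.08, camera adjusted p = 0.13), and the list passed without PBS replicate 1 (-0.14, adjusted p = 0.00329) and without both PBS replicate 1 and LPS replicate 2. The gene was Dio3, which inactivates thyroid hormone. It fell from 125 ± 128 to 3.6 ± 0.904 CPM (n = 4 per group; -5.12, SE 0.71, adjusted p = 0.00279), with 315 CPM in PBS replicate 1 and a value of -4.11 without it.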

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

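The tests of the patterns below were chosen after the values were seen, except the counts over other splits of the libraries. For the genes, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many changed genes (2729). The same held for genes changed at least 2-fold (1270), and the highest other split gave 1 in each case. Every other split mixes PBS and LPS libraries, which puts the treatment difference into the spread within groups and lowers its count. The splits thus argue against chance for the genes but do not exclude it, as 1 of 35 is the smallest share they can give. For the lists chance stays open: 3 of the 35 splits called at least as many as the real 18, with 20 as the highest.

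A library stood far from the other 3 of its group in 19 of 204 group values examined (9.31%). Chance gives about 1 in 20 for independent values with a normal spread. The gene values were CPM without a log scale, and many values move together, so the share does not show an excess over chance. The ratio given is the gap to the nearest library over the range of the group. LPS replicate 3 stood apart, at the high end, for Ptx3 (0.961), Ccl4 (0.863), Relb (0.94), Ednra (0.884), Il6 (0.913), Ccl2 (0.936) and Has2 (0.955), and at the low end for Krt7 (0.88). Its mean log2 CPM was highest for pyroptosis genes (0.835) and lowest for decidua and placenta markers (0.83). LPS replicate 4 was highest for Mmp8 (0.91), and LPS replicate 2 lowest for adipocyte and nerve markers (0.862). Among controls, PBS replicate 4 was highest for Il1b (0.869) and Nfkb2 (0.871) and lowest in total counts (0.893). PBS replicate 1 was highest for Oasl (0.883), Casp4 (0.908) and Dio3 (0.844), and PBS replicate 2 lowest for pyroptosis genes (0.893).

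Ifit1, an interferon-induced gene, was near the floor in LPS replicate 3 (0.532 CPM, 21 counts) and high for a control in PBS replicate 1 (26.7 CPM). A weaker interferon response of LPS replicate 3 is argued against, since the other 28 interferon genes lay above the other LPS libraries there by a median of 0.44 on the log2 scale, 5 of them below. A sequence variant of Ifit1 in these outbred animals, or reads taken by a related gene, stays open without reads: Ifit3 was higher in LPS replicate 3 by 1.06, but other interferon genes were too, by up to 1.52. An interferon response in PBS replicate 1 also stays open, since 27 of the 28 genes were above the other PBS libraries, by a median of 0.61.

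Most transcripts of autonomic neurons were lowest in PBS replicate 1 and LPS replicate 2, the 2 lowest libraries for 16 of 23 such genes: Tubb3 lay at 2.94 and 6.60 CPM there and at 11.1 to 48.2 CPM in the others, while Npy, at 22.9 CPM in PBS replicate 1, was not low in that library. Low depth is argued against, since the shallowest library, PBS replicate 4, lay 2.54 above the higher of the pair in mean log2 CPM of the 23 genes. LPS, which PBS replicate 1 did not receive, stays open for LPS replicate 2, although another LPS library lay 1.46 above the lowest of PBS replicates 2 to 4. A piece of tissue with little or no ganglion is a candidate explanation that cannot be told apart from other differences between animals. Of 10 neuron genes not looked at before, 4 had these as their 2 lowest libraries. Chance gives 3.57% of genes if they vary independently, but the estimated correlation between the 23 genes was 0.848. The 10 genes are thus not separate observations, and that share is no measure for them. The bound had been set at 6 of 11, and the last of the 11 was too low to test.

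The falls of Abcb1b, Cyp26a1 and Dio3 came with high levels in PBS replicate 1. Less of a tissue part that this library held most of stays open: of the 57 other genes at least 2.5-fold higher there than in each other PBS library, with a mean of at least 2 CPM, 7.02% fell by 3 or more on the log2 scale without that library, between the bounds of 5% and 25%. That share rests on 4 genes, among them Adprhl1 (-4.23), Wfdc16 (-3.41) and Ceacam9 (-3.35). Adprhl1 had already been named as a large fall highest in this library. Wfdc16 was not called in the fit of all libraries (adjusted p = 0.0545). Without that library the median of the 57 was -0.08, and Abcb1b, Cyp26a1 and Dio3 fell by 4.52, 4.98 and 4.11. A first version of this test, with a stricter choice of genes, went against the explanation. It was replaced because it left out genes that go with it. Lower progesterone signalling, a hypothesis, stays open too: 3 of 16 other progesterone-regulated genes fell (Bmp2, Errfi1 and Fkbp5), 0 rose, and their median was -0.21. Errfi1 and Fkbp5 are also glucocorticoid response genes of the fixed list. They had been tested there before the progesterone list was chosen, so their falls are no separate support. The call of Errfi1 was lost without PBS replicate 2 or LPS replicate 1, 2 or 3.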

How the results depend on the processing

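Of the 68 called genes named by the rule, 59 kept their call and direction with each library left out and 49 under every setting run. The called genes kept their sign in every fit of all 8 libraries and with any one left out. Without 1 library, 904 to 1385 genes were higher and 563 to 1199 lower, 568 to 765 at least 2-fold higher and 295 to 488 at least 2-fold lower, 11 to 12 lists higher and 5 to 7 lower, and 0.965 to 0.987 of the variance of component 1 lay between groups. Fewer libraries were tested in these fits. The filter was run anew in each, which left 16320 to 16375 genes. List counts without 1 library can thus include members that were not tested with all libraries. DESeq2 gave 2089 lower genes and fry called 3 lists lower, and the cause was not tested. Camera with an estimated correlation called 0 lists higher and 0 lower. That run used the same data with the correlation between genes estimated for each list. The estimates ran from 0.0665 (skeletal muscle markers) to 0.862 (smooth muscle markers), all above the preset 0.01.

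Directions of the test that turned belonged to lists that passed in neither case. The median of skeletal muscle markers was 0.49 by fry, 0.43 without both PBS replicate 1 and LPS replicate 2, and 0.18 to 0.69 without 1 library, but -0.74 with no filter on low counts and -1.09 with the stricter filter. That of cell cycle genes was -0.14 to 0.13 without 1 library. Without both named libraries it was -0.36 for glucocorticoid response and -0.0323 for clock genes. The cause was not tested. That fit, chosen after seeing the data, gave 697 genes at least 2-fold higher, 417 at least 2-fold lower, 11 lists higher and 8 lower.

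The replicate number as a block gave 1151 higher and 845 lower genes, called the list of steroid receptors and metabolism and did not call that of fibrillar collagen and matrix assembly. The labels do not say that numbers pair animals. Pairing was checked on log2 CPM less each gene's group mean. On these differences same-number libraries correlated at -0.18 to 0.21, and 2 of 8 libraries correlated best with their own number. Both were replicate 4, which in LPS has a library name with the number 5, so this pair shares a number by title alone. Depth limits genes near the floor of 0.0734 to 0.0899 CPM, where 3 counts lie.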

Other observations

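The gene lists and tests in this part were chosen after the data were seen. All 13 genes of MHC class I presentation rose, also adjusted over the list alone, with a median log2 fold change of 1.496 (camera adjusted p = 1.05e-23, adjusted p = 0.125 with an estimated correlation). Psmb9, a subunit of the immunoproteasome, rose by 1.93 (adjusted p = 0.00131) and Nlrc5, which drives class I genes, by 1.96 (adjusted p = 0.0004). Of 10 genes of MHC class II presentation, 1 rose and 0 fell, Rfx5 (0.58, adjusted p = 0.0041), with a median of -0.01 (camera adjusted p = 0.902). The 2 lists share 0 genes, and the difference between them was not tested. Of 21 endoplasmic reticulum chaperones and their regulators, 15 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 0.62 (camera adjusted p = 2.27e-11, adjusted p = 0.157 with an estimated correlation), among them Pdia4 (1.17, adjusted p = 0.00212) and Hsp90b1 (1.10, adjusted p = 0.00235). Cyp11b1, which makes glucocorticoids in the adrenal, rose from 0.103 ± 0.0959 to 11.4 ± 4.52 CPM (n = 4 per group; adjusted p = 0.0004), by 6.80, or by 7.54 without PBS replicate 4. Star, which brings cholesterol to the first step of that pathway, was at 0.424 ± 0.214 CPM in LPS (adjusted p = 0.517). The kininogen gene Kng2 rose from 0.0513 ± 0.0278 to 6.93 ± 4.38 CPM (adjusted p = 0.000852), with close copies that could share its reads.

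Of the 13 protein genes of the mitochondrial genome, 9 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 6.1e-08, adjusted p = 0.231 with an estimated correlation). Without PBS replicate 2, 4 fell. Of 92 respiratory chain genes of the nucleus, 2 rose and 2 fell, with a median of 0.02. Of 11 markers of peripheral glia, 4 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -1.30 (camera adjusted p = 5.97e-06, adjusted p = 0.157 with an estimated correlation). Mal, a myelin protein, fell by 1.78 (adjusted p = 0.00172). Of 23 autonomic neuron genes, 1 fell and 0 rose, also adjusted over the list alone (median -0.46, camera adjusted p = 0.467), and it was Npy (-2.51, adjusted p = 0.0197), a call lost without PBS replicate 2 or LPS replicate 3. The list passed without PBS replicate 1 or LPS replicate 1, with a median of -1.43 without the latter. Of 10 adipocyte genes 0 rose and 0 fell (median -0.77, camera adjusted p = 0.081), and the list passed without PBS replicate 3 or LPS replicate 4, the latter with 1 gene lower. Of 7 platelet genes, 3 fell and 1 rose (4 and 1 adjusted over the list alone; median -0.84, camera adjusted p = 0.263), and the list passed without PBS replicate 3, with a median of -1.44. Those that fell were Tubb1, Clec1b and Itga2b, and the call of Clec1b was lost without any one library other than LPS replicate 4, that of Itga2b without any one other than PBS replicates 3 and 4. Without PBS replicate 1 or 2, 1 platelet gene fell. Of 9 genes of goblet cell secretion, 2 rose and 2 fell (2 and 4 adjusted over the list alone; median -0.55, camera adjusted p = 0.263), and 1 rose without any one library other than PBS replicate 1 and LPS replicate 1. Agr2 rose by 1.48 (adjusted p = 0.00282) and Clca1 fell by 1.70 (adjusted p = 0.00355), and the list passed without PBS replicate 1. Of 16 progesterone-regulated uterine genes, without 3 that had been listed because they fell, 3 were lower and 0 higher (4 and 0 adjusted over the list alone; median -0.21, camera adjusted p = 0.0598, adjusted p = 0.218 with an estimated correlation, fry adjusted p = 0.0119).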
